A study of Mus musculus with 48 samples.

How the data were processed

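RNA of the left ventricular myocardium was measured on 48 Illumina mouse bead arrays, 1 array per heart. The hearts came from male C57BL/6 mice of 4 ages, and each was perfused outside the body either without interruption or through ischaemia and reperfusion (I/R). The 8 groups of age and treatment held 6 hearts each, as the labels give them. A heart can be collected only once, so no heart was shared between groups. Biotin-labelled cRNA was made with a TotalPrep amplification kit, per the labels' protocols, which also give an RNA integrity number (RIN) for each sample.

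The deposited signal is a probe intensity on a linear scale that was not normalized, per the file headers, and its values show that no background was subtracted. The deposited column headed as a detection p-value rises with the signal on every array (lowest rank correlation 0.995). It was therefore taken as 1 minus the detection p, a fraction between 0 and 1 deposited to 2 decimals without further processing. The table of processed values that the authors deposited is on a scale close to log2, and lumi is the tool named in the submitters' processing notes, with no version. Its transform and its normalization between arrays are not stated. Set against the signal of the same array, each of its 48 columns was closest to its own array and kept the rank order of the signal, with a slope on log2 signal of 0.916 to 1.05 over 6999 bright probes. The column medians lay between 7.812 and 7.83 and the values between 7.27 and 16.33. These values were not centred by gene, their direction is that of the signal, and their exact transform and their normalization between arrays stay unknown. They served as an alternative.

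The table of signals held 46628 lines, of which 4 had no probe identifier and were left out, which left 46624 probes. The platform's annotation gave a single gene symbol for 29971 probes, several for 10 and none for 16643. The symbols of 29916 probes were updated through their Entrez number. Probes with several symbols were not named.

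The signals were corrected for background and normalized with limma 3.58.1 in R 4.3.3, with statmod 1.5.0 installed for limma. The files were read with the R package data.table (version 1.17.8). The background was estimated from the detection p-values (normexp, offset 16), followed by quantile normalization and log2. A probe was kept when its detection p was under 0.05 on at least 6 of the 48 arrays, which left 17624 probes, 4074 of them without a gene symbol. Each gene was represented by its probe with the highest mean over all arrays, which gave 9811 genes. For 2813 of these genes at least 2 probes were detected, and the next brightest probe was used as a check on the first.

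A linear model with a mean for each of the 8 groups was fitted to all 48 arrays with limma (lmFit and eBayes), so that all groups shared 1 estimate of the spread per gene. The comparisons were 16, 32 and 48 weeks against 8 weeks, 32 against 16 weeks and 48 against 32 weeks in normoxic hearts, any age difference in normoxic hearts (F test), I/R against normoxic hearts at each age and as the mean over ages, the dependence of the I/R difference on age (F test over ages, and 48 against 8 weeks), and 48 against 8 weeks in I/R hearts. Tests were two-sided, p-values were adjusted over all genes by the Benjamini-Hochberg method within each comparison, and the threshold was an adjusted p under 0.05. Values per gene are log2 fold changes with the model's standard error (SE). A probe not detected on any array of 1 group or treatment has only a bound there. Its fold is given as at least the mean of the bright group over the mean of the dim group, in which each dim array took the higher of its lowest detected signal and the probe's own. Where only some arrays of the dim side detected a gene's probe, their number is given, and for leading I/R genes missed on most arrays of that side also the fold against that raised level.

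Gene lists comprised 23 pathways and 14 sets of cell type markers, and the 32 lists with at least 5 measured members were tested. The test was camera from limma with a preset correlation of 0.01 between genes, which compares a list with all other genes, adjusted over the lists. The same test with a correlation estimated from the data was the alternative. The members of a list past the threshold were counted over all genes and again adjusted over the list alone.

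The genes named in the text follow a rule. For 48 against 8 weeks in normoxic hearts and for the mean I/R difference these are the 8 largest changes in each direction among genes past the threshold that were detected on all arrays of at least 1 of the groups or treatments compared. For 48 against 8 weeks in I/R hearts and for each step of age in normoxic hearts they are the 4 largest in each direction under the same condition. For the dependence of the I/R difference on age they are the 10 genes with the smallest p. For each list they are up to 4 members with the smallest p where the list passes and 1 otherwise, in the comparisons with 8 genes in each direction. Where no gene passed, the 3 with the smallest p are named. Other genes are said to be chosen after their values were seen. Since named genes were chosen on these same arrays, the number of their hearts on the side of the change is no separate support. The groups, comparisons, tests, lists, naming rule and first set of alternatives were chosen before the data were examined.

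The fit and the list test were tested on simulated data made from each gene's mean and spread on these arrays, in which 67 genes were changed 1.3-fold, 67 were changed 1.5-fold and 66 were changed 2-fold. For 48 against 8 weeks in normoxic hearts, over 9811 genes, 22.4% of the genes changed 1.3-fold, 59.7% of those changed 1.5-fold and 93.9% of those changed 2-fold were recovered, with 5 unchanged genes called. For the mean I/R difference the shares were 79.1%, 98.5% and 98.5%, with 9 unchanged genes called. In the simulated list test the moved list was found and 0 others were called by camera. The simulated genes were drawn independently of each other. That test therefore cannot show how often lists are wrongly called where genes are correlated.

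The alternatives were no background correction, median centring in place of quantile normalization, the authors' values (which differ in background correction, transform and normalization at once), no filter or a stricter filter on dim probes (p under 0.01 on all arrays of a group), all probes tested singly, array weights, the replicate number as a block, RIN as a covariate, only the groups compared in the fit, eBayes with trend and robust settings, a fold of at least 1.3, and an estimated correlation in the list test. A fit with the slide as a block was planned but could not be made, since neither the labels nor the deposited tables name a slide, run or scan date. Arrays carry no depth of reads, and their number limits the precision. Other splits of the same arrays, 100 for each comparison, were drawn with a fixed seed. Added after the data were seen was a count of genes with both of their brightest probes past the threshold in the same direction. For the F tests, which give no direction, both probes had only to pass. Fits without each array in turn for 32 and for 48 against 8 weeks in normoxic hearts were also added. Contrasts over other sets of ages were added as well. Probes without a gene symbol were fitted apart from the genes.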

Results

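RNA was profiled in the left ventricular myocardium of 48 male mice that were 8, 16, 32 or 48 weeks old. Every heart was perfused in isolation (Langendorff mode) and stabilised for 20 min. At each age 6 hearts then went through 25 min of ischaemia and 45 min of reperfusion (I/R), and 6 were perfused with oxygenated buffer for the same time (normoxic hearts). The age comparisons ask which transcripts differ between young and middle-aged hearts, and the I/R comparisons ask how the reperfused ventricle differs from the perfused one and whether that depends on age.

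The arrays of the 2 treatments differed in quality measures. RIN was 8.50 ± 0.296 (SD, n = 24) in normoxic hearts and 7.87 ± 0.296 (SD, n = 24) in I/R hearts, and in I/R hearts its mean was 8.08 at 8 weeks, 8.03 at 16 weeks, 7.75 at 32 weeks and 7.60 at 48 weeks. In normoxic hearts it was 8.52, 8.75, 8.42 and 8.30 at these ages. The background signal lay between 121.2 and 141.1 on normoxic arrays and between 144 and 181 on I/R arrays, without overlap. Normoxic arrays detected 13362 to 15080 probes, and I/R arrays detected 11072 to 13854. The principal component with the largest share of the variance over all genes held 55.9% of it, and the next held 7.98%. No slide, run or date is given for any array, so a batch that follows the treatment cannot be told apart from the treatment. Each age is a separate set of animals, so a batch that follows the age cannot be told apart from age either, in normoxic or in I/R hearts.

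In normoxic hearts the largest increases from 8 to 48 weeks included enzymes, trafficking genes and a chemokine. Cds1, which makes CDP-diacylglycerol for phospholipid synthesis, rose from a mean log2 level of 6.66 to 8.51 (log2 fold change 1.85 ± 0.152, SE, n = 6 per group, adjusted p = 8.33e-12). Rab4a, a small GTPase of endosomal recycling, rose by 1.81 ± 0.182 (adjusted p = 1.69e-09), and Ccl11, the eosinophil chemokine eotaxin, rose by 1.76 ± 0.224 (adjusted p = 9.04e-07). Sh3gl2, an endophilin of vesicle endocytosis, rose by 1.64 ± 0.261, and Abat, the transaminase that degrades GABA, rose by 1.58 ± 0.31. Replicate 2 of the 48-week hearts lay below the other 5 in Cds1 and in Sh3gl2.

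The largest decreases from 8 to 48 weeks included an ion channel subunit, an amine-producing enzyme, the transferrin receptor and matrix genes. Kcne1, the accessory subunit of the slow delayed-rectifier potassium channel, fell 4.69-fold (log2 fold change −2.23 ± 0.279, SE, n = 6 per group, adjusted p = 6.43e-07). A dimmer probe of Kcne1 gave −0.33 (adjusted p = 0.402). Ddc, the aromatic amino acid decarboxylase that makes dopamine and serotonin, was at least 2.41-fold lower (adjusted p = 1.69e-09), since no 48-week heart had this probe detected, and its second probe gave −1.33. Tnni2, the troponin I of fast skeletal fibres, fell 2.53-fold (adjusted p = 3.49e-06, detected in 5 of 6 48-week hearts), and Tfrc, which takes up transferrin-bound iron, fell 2.39-fold (adjusted p = 0.00663). Col1a1, a chain of type I collagen, fell 2.14-fold (adjusted p = 0.00116). Ramp1, part of the receptor for calcitonin gene-related peptide, fell 2.06-fold (adjusted p = 0.00532), and Eln, which encodes elastin, fell 1.99-fold (adjusted p = 0.0176).

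**Figure D1:**
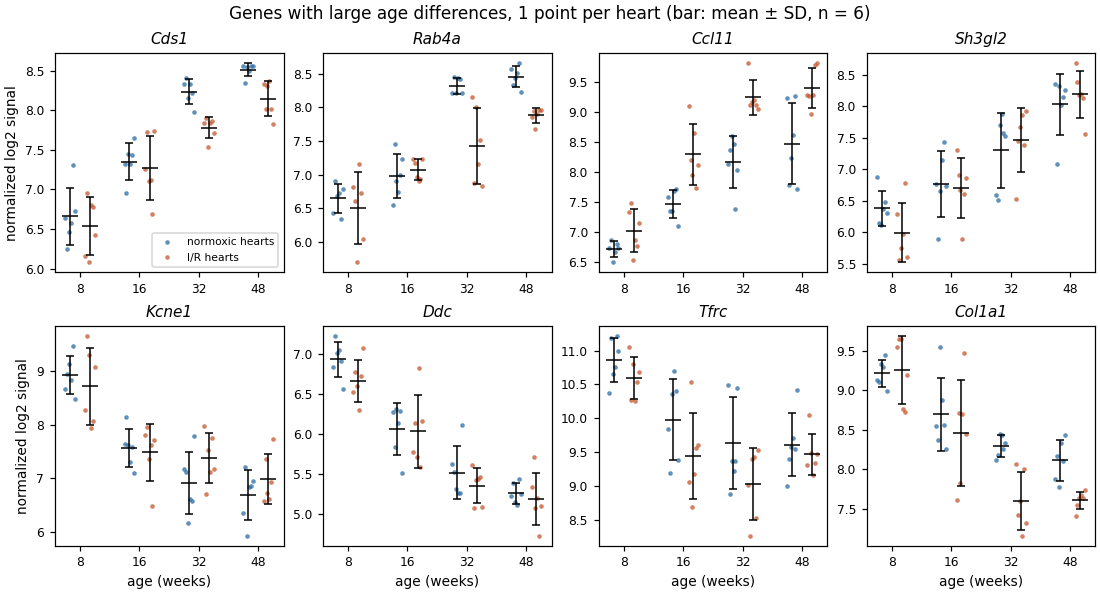
Log2 levels of 8 genes in normoxic and I/R hearts of 4 ages, with 1 point per heart and the mean ± SD of 6 hearts per group. In normoxic hearts Cds1 is 3.61-fold higher and Kcne1 is 4.69-fold lower at 48 than at 8 weeks.

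In all, 161 of 9811 genes were past the threshold between 48 and 8 weeks, 89 higher and 72 lower; with median centring it was 97 and 91, in the authors' values 99 and 104, and with array weights 187 and 172 (359 genes). In each of the 16 genes with the largest changes 6 of 6 hearts lay on the side of the change. Those not named above were Klk1b26, a kallikrein-family protease (log2 fold change 1.71, second probe 1.83, detected in 3 of 6 8-week hearts), the amylase Amy2a5 (1.63), BC048679 (at least 1.91-fold higher, since no 8-week heart had it detected) and the metalloprotease Adamts12 (−0.81, detected in 1 of 6 48-week hearts), whose dimmer probe gave 0.07. Klk1b26 and Amy2a5 have close paralogs, so which family member was measured is uncertain.

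Matrix genes as a group were lower at 48 than at 8 weeks in normoxic hearts, whose mean RIN was 8.30 and 8.52. Of 29 collagen and matrix genes 7 were lower and 0 were higher, and 13 passed when adjusted over the list alone (median log2 fold change −0.26, adjusted p = 1.88e-09, or adjusted p = 0.118 with an estimated correlation). Col6a1, a chain of type VI collagen, fell 1.53-fold (adjusted p = 0.00154), in 6 of 6 hearts, and its second probe gave −0.63. The basement membrane collagen Col4a2 fell 1.60-fold (adjusted p = 0.00382), in 6 of 6 hearts. Sparc, a collagen-binding matrix protein, fell 1.64-fold (adjusted p = 0.00333), but its p was 0.255 in the authors' values and 0.151 without background correction. Outside the list, the gelatinase Mmp2 fell 1.41-fold (adjusted p = 0.00726) and vitronectin, Vtn, fell 1.43-fold (adjusted p = 0.00739, or 0.0535 with only the groups compared in the fit), each in 6 of 6 hearts. Only 1 of 14 fibroblast markers was lower, Col1a1 itself, and that list did not pass (adjusted p = 0.245).

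Inflammatory genes as a group were higher at 48 than at 8 weeks in normoxic hearts (mean RIN 8.30 and 8.52). Of 28 cytokine and NF-kappaB target genes 4 were higher and 0 were lower, and 8 passed when adjusted over the list alone (median 0.50, adjusted p = 2.79e-10, or adjusted p = 0.339 with an estimated correlation). The cytokine Il6 rose 2.34-fold (log2 fold change 1.23 ± 0.26, SE, n = 6 per group, adjusted p = 0.00403), but its p was 0.266 in the authors' values and 0.132 without background correction, and replicate 4 of the 8-week hearts lay below the other 5 (Il6 was detected in 5 of these 6). The adhesion molecules Vcam1 and Sele rose 1.80-fold (adjusted p = 0.01) and 1.89-fold (adjusted p = 0.0482), and the monocyte chemokine Ccl7 rose 1.79-fold (adjusted p = 0.0377), each in 6 of 6 hearts. Under 11 alternatives Sele did not pass in 4 (highest adjusted p = 0.0766) and Ccl7 in 2 (0.0603). Markers of macrophages and monocytes did not pass (0 of 14 genes, adjusted p = 0.215). Immediate early genes were also higher, 3 of 29 over all genes and 3 adjusted over the list alone (adjusted p = 0.000507, or adjusted p = 0.734 with an estimated correlation). The neuronal activity gene Arc rose 2.30-fold (adjusted p = 0.00403) and the transcription factors Egr2 and Egr1 rose 1.79-fold (adjusted p = 0.0176) and 1.34-fold (adjusted p = 0.0415), in 6 of 6 hearts each. Under 11 alternatives Egr1 did not pass in 5 (highest adjusted p = 0.0684) and Egr2 in 1 (0.0558). With the preset correlation, the immediate early list was lower at 16 and at 32 weeks than at 8 weeks, and higher at 48 than at 32 weeks. The inflammatory list passed for 48 against 32 weeks, but not for 16 or 32 against 8 weeks. Both rises therefore rest on the 6 normoxic hearts of 48 weeks.

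**Figure D2:**
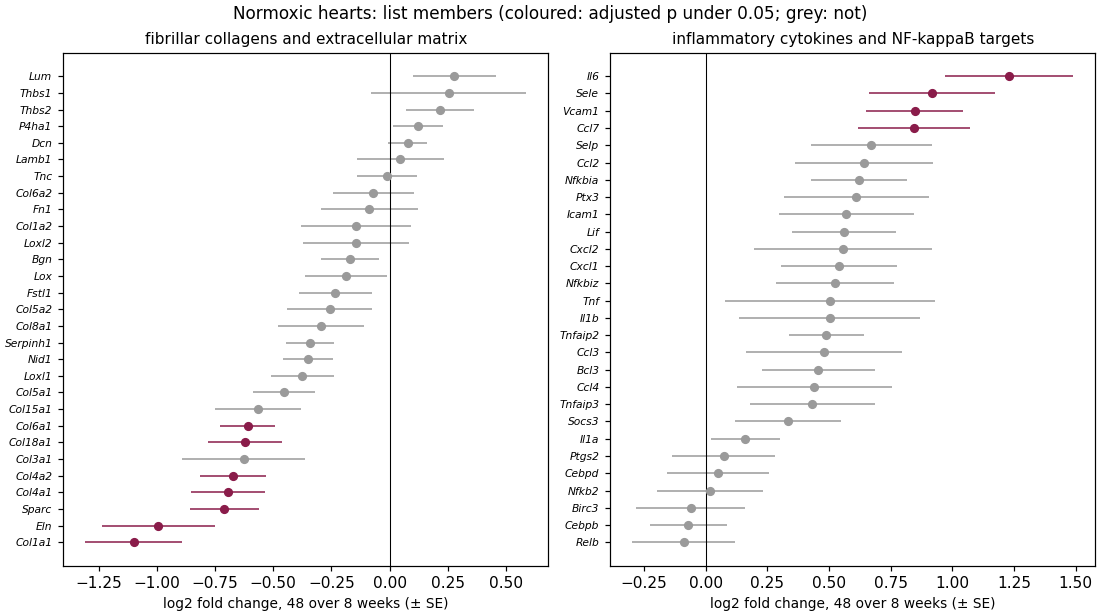
Log2 fold change ± SE between 48 and 8 weeks in normoxic hearts for the members of the matrix list and of the inflammatory list, 6 hearts per age, coloured where the adjusted p over all genes is under 0.05. Of the matrix genes 7 of 29 passed, all lower, and of the inflammatory genes 4 of 28 passed, all higher.

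The other 5 lists that passed held muscle, metabolic, oxidative stress and endothelial genes. Skeletal muscle genes were lower (2 of 6, and 3 adjusted over the list alone; adjusted p = 0.00372, or adjusted p = 0.099 with an estimated correlation), through Tnni2 and the muscle creatine kinase Ckm, which fell 1.22-fold (adjusted p = 0.0377) but did not pass in 4 of 11 alternatives (highest adjusted p = 0.163). Subunits of oxidative phosphorylation were lower by a median of −0.04 (adjusted p = 0.048, or adjusted p = 0.734 with an estimated correlation), and of 55 only Cyc1, the cytochrome of complex III, passed over all genes (−0.30, adjusted p = 0.00762, or 0.0547 with median centring) and over the list alone. That list did not pass with median centring (adjusted p = 0.24) or in the authors' values (adjusted p = 0.0567). Genes of fatty acid use had a median of 0.12 (adjusted p = 0.00573, or adjusted p = 0.463 with an estimated correlation), and 0 of 30 passed over all genes or over the list alone. In the oxidative stress list (adjusted p = 0.0118, or adjusted p = 0.458 with an estimated correlation) 0 of 18 genes passed over all genes and 1 passed over the list alone. The endothelial list was lower (median −0.17, adjusted p = 0.00845, or adjusted p = 0.47 with an estimated correlation), with 0 of 18 genes over all genes and 1 over the list alone. Each of these lists was tested with limma, in a comparison with 1009 genes at an unadjusted p under 0.05. The other 24 of the 32 lists did not pass, with adjusted p from 0.157 to 0.992, among them heat shock (0.992), calcium handling and ion channels (0.942), sarcomere genes (0.992) and hypertrophy genes (0.992).

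Age differences were already present at 32 weeks, and 4 genes differed at 16 weeks (20 with array weights, 8 with median centring, 2 with RIN as a covariate or with all probes tested singly). At 16 weeks Amy2a5 was 1.89-fold higher than at 8 weeks (adjusted p = 0.0105), Aox1, an aldehyde oxidase, was 1.60-fold higher (adjusted p = 0.04), Kcne1 was 2.56-fold lower (adjusted p = 0.04) and Ddc was 1.82-fold lower (adjusted p = 0.0235, detected in 5 of 6 16-week hearts), each in 6 of 6 hearts. These 4 genes were all that passed, and the dimmer probes of Aox1 and Kcne1 gave 0.03 and −0.34. Under 11 alternatives Aox1 did not pass in 4 (highest adjusted p = 0.0999) and Kcne1 in 2 (0.107). Between 16 and 32 weeks 5 genes passed (11 with median centring, 10 with array weights and 8 with the strict filter), each in 6 of 6 hearts. Wdfy1, an endosomal adaptor, rose 3.20-fold (adjusted p = 0.00148), Rab4a rose 2.53-fold (adjusted p = 1.51e-05) and Cds1 rose 1.84-fold (adjusted p = 0.00148). The nucleoside diphosphatase Entpd4 fell 1.85-fold (adjusted p = 1.43e-06) and Tnni2 fell 1.82-fold (adjusted p = 0.0402), though it did not pass in 2 of 11 alternatives (highest adjusted p = 0.135).

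At 32 weeks 154 genes differed from 8 weeks, 78 higher and 76 lower (91 and 144 with median centring, 105 and 128 in the authors' values, 204 and 204 with array weights), and that count of 154 fell to 94 without replicate 2 of the 8-week hearts and to 102 without replicate 5 of the 32-week hearts. Over all ages of normoxic hearts 164 genes differed (F test), or 438 with array weights. Matrix genes were lower at 32 weeks (6 of 29, and 12 adjusted over the list alone; adjusted p = 1.52e-08, or adjusted p = 0.15 with an estimated correlation) and at 16 weeks (0 of 29 over all genes by limma, 5 adjusted over the list alone; adjusted p = 6.33e-06, or adjusted p = 0.3 with an estimated correlation). Between 32 and 48 weeks 0 genes passed by limma, with 504 at an unadjusted p under 0.05; 11 passed in the authors' values and 19 with array weights. The genes with the smallest p there were Edn1, which encodes endothelin (log2 fold change 0.80), the adipokine C1qtnf9 (−0.57) and the cell cycle inhibitor Cdkn1a (0.91, second probe 0.90), none past the threshold (adjusted p = 0.155 each). In Cdkn1a, replicate 6 of the 48-week hearts lay below the other 5.

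Between I/R and normoxic hearts the largest increases, as the mean over ages, included metabolic and mitochondrial genes, a chaperonin and a cytokine. Selenop, which transports selenium, was 10.7-fold higher in I/R hearts (log2 fold change 3.43 ± 0.0759, SE, n = 24 per treatment, adjusted p = 3.19e-35). Glul, the glutamine synthetase, was 10.6-fold higher and Cct5, a subunit of the cytosolic chaperonin, was 10.4-fold higher. Pmpcb, which trims imported mitochondrial proteins, was 9.77-fold higher, Mdh2, the mitochondrial malate dehydrogenase, was 8.96-fold higher, and Atp5e, a subunit of the ATP synthase, was 9.33-fold higher. Calm2, a calmodulin gene, was 9.47-fold higher and Il6 was 9.30-fold higher (adjusted p = 4.95e-26, detected in 23 of 24 normoxic hearts). In Cct5, replicate 6 of the 16-week normoxic hearts and replicate 5 of the 16-week I/R hearts lay above the other hearts of their groups. Most normoxic hearts did not have Cct5 (2 of 24 detected), Glul (3 of 24) or Calm2 (6 of 24) above background, and with the normoxic side raised to the lowest detected signal their folds were 7.20, 7.47 and 8.32. None of these 8 genes had a second detected probe.

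The largest decreases with I/R included genes of signalling, trafficking, adhesion and transcription. Trib3, a stress-response pseudokinase, was 6.42-fold lower (log2 fold change −2.68 ± 0.0848, SE, n = 24 per treatment, adjusted p = 4.73e-30), and its second probe gave −1.27. Gna12, a G-protein alpha subunit, was 5.06-fold lower, and Lbh, a transcription cofactor of the developing heart, was 4.69-fold lower. Lmcd1, a LIM-domain regulator of cardiac transcription, was 4.18-fold lower, with −2.33 from its second probe. Bcam, a laminin receptor, was 4.14-fold lower (second probe −1.72), and Ctnnd1, a catenin that stabilises cadherins, was 4.13-fold lower (second probe −0.89). The clathrin adaptor Ap2a1 was 4.30-fold lower and Isoc2a was 4.83-fold lower. Of the 24 I/R hearts 4 had Trib3, 4 Bcam, 4 Isoc2a, 6 Gna12 and 10 Ap2a1 above background by the brightest probe, and with the I/R side raised to the lowest detected signal their folds were 4.84, 2.63, 3.80, 3.87 and 3.42. In all 16 genes 24 of 24 I/R hearts lay on the side of the change, which choosing the largest changes favours. The largest adjusted p among the decreases was 5.47e-25.

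**Figure D3:**
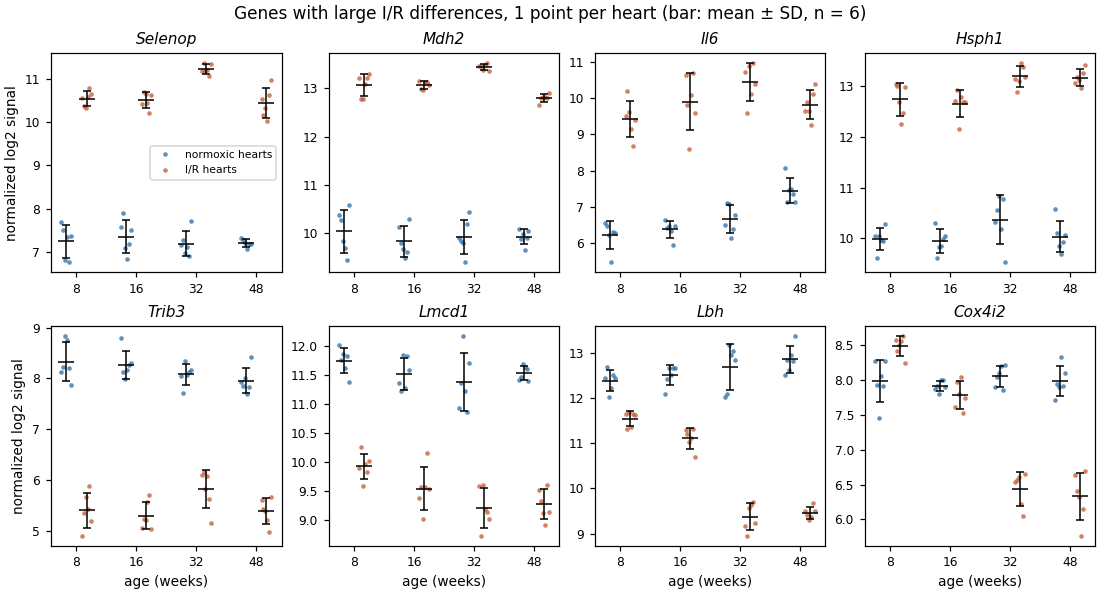
Log2 levels of 8 genes in normoxic and I/R hearts at each age, with 1 point per heart and the mean ± SD of 6 hearts per group. Selenop is 10.7-fold higher and Lmcd1 is 4.18-fold lower in I/R hearts as the mean over ages.

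The difference between treatments covered most genes: 7743 of 9811 (78.9%) passed, 3390 higher and 4353 lower. The excess of lower genes was not kept in every setting: 4051 were higher and 4025 lower with median centring, and 5156 and 5178 without a filter on dim probes. Of the 6765 genes that passed with both scalings 221 had opposite signs. The count was 5192 at 8 weeks, 5331 at 16 weeks, 6440 at 32 weeks and 6219 at 48 weeks. The median log2 fold change of all genes was −0.07. Of 1888 genes with both of their brightest probes past the threshold, 1074 had them in the same direction and 814 (43.1%) in opposite directions. Over the 554 genes with a pair of bright probes, the log2 fold changes of the pair correlated across genes at r = 0.0812 (95% interval −0.00603 to 0.168) for I/R, against r = 0.692 (0.578 to 0.774) for 48 against 8 weeks in normoxic hearts, where 9 of 9 such genes had the same direction. Genes are not independent replicates. The I/R value of a gene measured by a single probe therefore describes that probe.

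**Figure D4:**
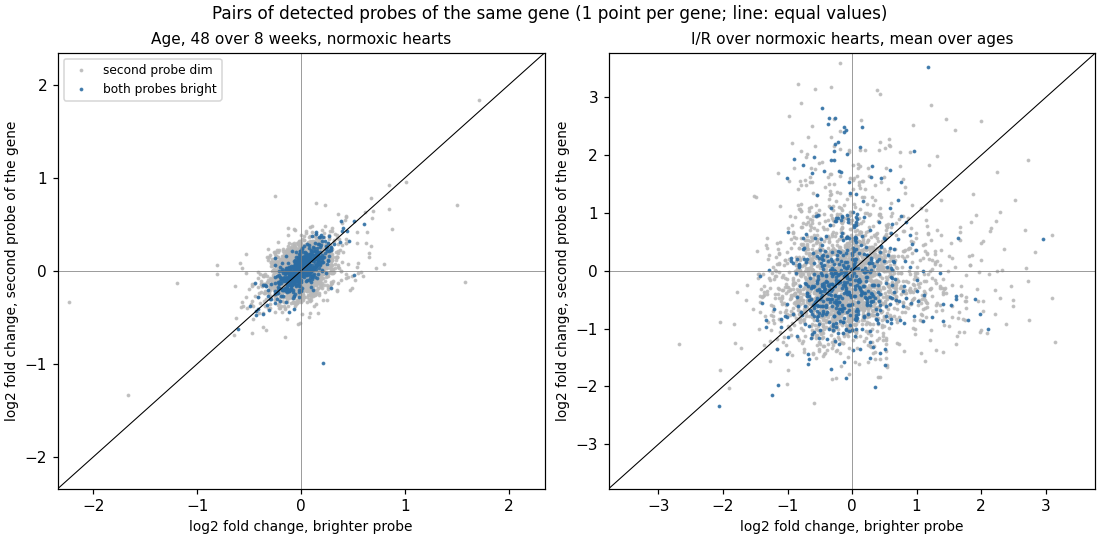
Log2 fold changes of the brightest probe and the next brightest probe of the same gene, for 48 against 8 weeks in normoxic hearts and for I/R as the mean over ages, with 1 point per gene and genes with a pair of bright probes in colour. Among bright pairs r is 0.692 for age and 0.0812 for I/R.

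Heat shock genes were the only list that passed for the mean I/R difference. Of 18 genes 11 were higher and 5 lower, and 16 passed when adjusted over the list alone (median 0.51, adjusted p = 0.0485, or adjusted p = 0.962 with an estimated correlation); with median centring of the arrays the list did not pass (adjusted p = 0.0524). The number of lists that passed was 0 with the strict filter and with the replicate block, 2 without a filter, and 3 with RIN as a covariate and in the authors' values. Hsph1, an HSP110 chaperone, was 7.26-fold higher (adjusted p = 1.34e-31) and Cacybp, a co-chaperone that binds calcyclin, was 8.06-fold higher (adjusted p = 1.12e-32, detected in 21 of 24 normoxic hearts). Both were so in 24 of 24 hearts. Hsp90aa1, the inducible HSP90, was at least 2.09-fold higher (adjusted p = 1.75e-26), since no normoxic heart had it detected, against 18 of 24 I/R hearts. Dnajb4, a co-chaperone of the HSP40 family, was 8.55-fold higher by its brightest probe, whereas its dimmer probe gave −0.48 (adjusted p = 1.43e-08). The list passed at 8 weeks (adjusted p = 0.00165, or adjusted p = 0.855 with an estimated correlation), at 16 weeks (adjusted p = 0.013, or adjusted p = 0.907) and at 32 weeks (adjusted p = 0.041, or adjusted p = 0.968, and 0.0535 with median centring), and 0 of 32 lists passed at 48 weeks. The list's change in the I/R difference between 8 and 48 weeks did not pass (adjusted p = 0.484).

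The other lists held genes that moved both ways with I/R, and none of the 31 passed. Among 29 immediate early genes 14 were higher and 12 lower (26 adjusted over the list alone, adjusted p = 0.555), and Klf4, a zinc-finger transcription factor, was 7.78-fold higher by its brightest probe and 0.54 higher on the log2 scale by its second. Among 28 inflammatory genes 14 were higher and 9 lower (23 adjusted over the list alone, adjusted p = 0.555), with Nfkbia, the inhibitor of NF-kappaB, 7.08-fold higher (detected in 23 of 24 normoxic hearts). Of 55 oxidative phosphorylation subunits 27 were higher and 22 lower (49 adjusted over the list alone, adjusted p = 0.555). Glycolysis genes were mostly lower, 14 of 23 against 4 higher (18 adjusted over the list alone, adjusted p = 0.118), and Ldha, the lactate dehydrogenase of muscle, was 1.80-fold lower (adjusted p = 3.58e-29, 24 of 24 hearts). At 32 weeks the glycolysis list passed, with 15 genes lower and 5 higher (20 adjusted over the list alone; adjusted p = 0.041, or adjusted p = 0.968 with an estimated correlation). In the unfolded protein list 7 of 17 genes were higher and 6 lower (12 adjusted over the list alone, adjusted p = 0.709), and Hspa5, the chaperone of the endoplasmic reticulum, was 7.83-fold higher (detected in 20 of 24 normoxic hearts).

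Marker lists of cell types did not pass for I/R either. Of 18 endothelial genes 5 were higher and 10 lower (15 adjusted over the list alone, adjusted p = 0.591), and Egfl7, secreted by endothelium, was 2.15-fold lower (second probe −0.83). Of 19 sarcomere genes 10 were higher and 6 lower (16 adjusted over the list alone, adjusted p = 0.555), and cardiac troponin T, Tnnt2, was 1.49-fold higher (adjusted p = 1.03e-20). Of 14 macrophage and monocyte genes 7 were higher and 4 lower (11 adjusted over the list alone, adjusted p = 0.555), with the macrophage receptor Adgre1 2.74-fold higher. Of 14 fibroblast genes 8 were higher and 5 lower (13 adjusted over the list alone, adjusted p = 0.555), with the matrix protein Dpt 2.40-fold higher. For 2 genes of other lists the probes opposed each other: Ndrg1, a hypoxia-responsive gene, had 1.03 and −0.53, and Fxyd1, the regulator of the sodium pump, had 1.40 and −0.58.

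The I/R difference depended on age for 2868 of 9811 genes (29.2%, F test over ages). Tle5, a corepressor of the Groucho family, had a log2 fold change with I/R of −0.08 at 8 weeks and −1.43 at 48 weeks, a change of −1.35 ± 0.107 (SE, n = 6 per group, limma F test, adjusted p = 9.42e-16). Selenow, a small selenoprotein, went from −0.20 at 8 weeks to −1.57 at 48 weeks (adjusted p = 1.97e-15), and Lbh went from −0.84 to −3.39 (adjusted p = 2.2e-13). Cox4i2, the oxygen-regulated isoform of a cytochrome c oxidase subunit, went from 0.50 to −1.65 (adjusted p = 1.5e-13). Decr1, a reductase of unsaturated fatty acid oxidation, went the other way, from 0.40 to 1.85 (adjusted p = 1.06e-13). Bcat2, the mitochondrial branched-chain aminotransferase, went from −0.46 to −1.63 (adjusted p = 9.11e-13). In each, 6 of 6 I/R hearts of 48 weeks lay on the side of the change, and none of these 6 genes had a second detected probe.

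For 3 of the other 4 genes with the smallest p, a second probe had the opposite sign or did not pass. For the mannosidase Man1b1 the change from 8 to 48 weeks was −1.76 by the brightest probe (detected in 5 of 6 48-week I/R hearts) and 0.28 (adjusted p = 0.306) by the other, and for the kinase subunit Csnk2a2 it was 0.93 and −0.62 (adjusted p = 0.022). For the reductase Cyb5r3 it was −0.95 and −0.31 (adjusted p = 0.365), and for Clptm1, with a single probe, it was −1.12. The I/R difference changed between 8 and 48 weeks for 2097 genes, 1006 higher and 1091 lower (1149 and 752 with median centring), between 8 and 32 weeks for 2255 and between 8 and 16 weeks for 1. Over bright pairs of probes the change from 8 to 48 weeks correlated across genes at r = 0.129, and among 100 genes with both probes past the threshold 35 had opposite directions.

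A set of 5 lists had lower I/R differences at 48 than at 8 weeks, each at adjusted p = 0.0428. With an estimated correlation none passed (adjusted p = 0.063 for angiogenesis and hypoxia, adjusted p = 0.871 for the other 4), and 0 lists passed with RIN as a covariate or with the strict filter. The mean RIN of I/R hearts was 8.08 at 8 weeks and 7.60 at 48 weeks. In these lists, 8 of 29 immediate early genes were lower and 1 higher (11 adjusted over the list alone), and 0 were higher in the rest. Lower were 4 of 28 inflammatory genes (4 adjusted over the list alone), 5 of 18 interferon genes (5 adjusted over the list alone), 6 of 18 autophagy genes (6 adjusted over the list alone) and 5 of 19 angiogenesis and hypoxia genes (6 adjusted over the list alone). In the authors' values the inflammatory list had an adjusted p of 0.0653 and the autophagy list 0.0505. The immediate early and inflammatory lists were higher at 48 than at 8 weeks in normoxic hearts, the reference of the I/R difference. Neither of them passed for 48 against 8 weeks in I/R hearts. For these lists the test cannot tell a weaker response to I/R from a higher normoxic level.

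In I/R hearts the chemokine Ccl11 also rose with age, 5.22-fold from 8 to 48 weeks (log2 fold change 2.38 ± 0.224, SE, n = 6 per group, adjusted p = 1.79e-11). The protease inhibitor Serpina3n rose 4.97-fold (adjusted p = 3.36e-08), Sh3gl2 rose 4.56-fold (adjusted p = 6.79e-09) and Abat rose 4.55-fold (adjusted p = 2.63e-07). At 8 weeks Sh3gl2 was detected in 3 of 6 and Abat in 4 of 6 I/R hearts, and against these 4 alone the rise of Abat was 2.57-fold. Cox4i2 fell 4.45-fold (adjusted p = 2.62e-17, detected in 5 of 6 48-week hearts) and Lbh fell 4.23-fold (adjusted p = 5.5e-14). Itga5, the fibronectin receptor integrin, was at least 2.55-fold lower, since no 48-week I/R heart had it detected, and Erdr1 fell 14.2-fold by its brightest probe (adjusted p = 7.76e-09), whereas a dimmer probe gave −0.56 (adjusted p = 0.0414); the brightest was detected in 3 of 6 48-week I/R hearts, and with that side raised to the lowest detected signal the fold was 9.47. In each of these 8 genes 6 of 6 hearts lay on the side of the change.

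Between 8 and 48 weeks the mean RIN of I/R hearts went from 8.08 to 7.60 and the mean number of detected probes from 13260 to 11800. Matrix genes were lower at 48 than at 8 weeks in I/R hearts too, with 17 of 29 lower and 3 higher (21 adjusted over the list alone; median −0.53, adjusted p = 0.000354, or adjusted p = 0.491 with an estimated correlation). Col1a1 fell by 1.64 on the log2 scale in I/R hearts and by 1.10 in normoxic hearts, a difference that did not pass (interaction adjusted p = 0.191). Interferon genes were lower, 10 of 18 with 0 higher (12 adjusted over the list alone; adjusted p = 0.00628, or adjusted p = 0.491 with an estimated correlation). In all, 3855 genes differed between 48 and 8 weeks in I/R hearts, 1829 higher and 2026 lower (2052 and 1636 with median centring), and among 386 genes with both of their brightest probes past the threshold 140 (36.3%) had opposite directions.

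Of the 161 genes that differed between 48 and 8 weeks in normoxic hearts, 125 (77.6%) had the same sign in I/R hearts, against 53.7% of all genes. Among them 104 passed in I/R hearts, 92 with the same sign (53 higher and 39 lower) and 12 with the opposite sign. Cds1 rose by 1.61 in I/R hearts (interaction adjusted p = 0.466), Kcne1 fell by 1.73 on the log2 scale (interaction adjusted p = 0.404) and Ddc, whose brightest probe was not detected in any 48-week heart, was at least 1.58-fold lower (interaction adjusted p = 0.602). The age differences of the 2 treatments correlated across genes at r = 0.26 over all 9811 genes (SD 0.048 over 100 resamples of the arrays) and at r = 0.809 over the 161. For 51 of the 161 genes the I/R difference changed between 8 and 48 weeks, against 2097 of all 9811 (21.4%). The 161 were chosen by the age difference of normoxic hearts, which is part of that change, so the choice itself favours such a call.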

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

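The comparisons of 2 probes of the same gene, the comparison with the age difference of normoxic hearts and the comparisons of hearts of like RIN, added once the slopes on RIN had decided nothing, were chosen as tests only after the result was seen.

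The I/R difference depended on age for 2868 genes by the F test over ages and for 2097 genes between 48 and 8 weeks, a difference between groups that the fit tested itself. Among the named genes the F test by the brightest probe gave the smallest adjusted p for the corepressor Tle5 (adjusted p = 9.42e-16), Selenow (1.97e-15), Decr1 (1.06e-13), Cox4i2 (1.5e-13), Lbh (2.2e-13), Cyb5r3 (3.66e-13), Man1b1 (3.71e-13), Clptm1 (4.01e-13), Bcat2 (9.11e-13) and Csnk2a2 (2.32e-12). Between 8 and 48 weeks the second probes of Man1b1 and Csnk2a2 changed with the opposite sign. The second probe of Cyb5r3 did not pass. Further adjusted p-values were 2.69e-07 for Itga5, 3.19e-07 for Ap2a1, 0.000316 for Glul, 0.000373 for Calm2, 0.000631 for Ctnnd1, 0.00271 for Atp5e, 0.00326 for Cct5, 0.00376 for Selenop, 0.00611 for Klk1b26, 0.00948 for Rab4a, 0.00959 for Erdr1, 0.0142 for Il6, 0.0221 for Bcam, 0.0253 for Tnni2, 0.0385 for Cdkn1a and 0.0489 for Trib3.

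Probes without a gene symbol, which the comparisons by gene did not use, also differed: 33 of 4074 between 48 and 8 weeks in normoxic hearts (23 higher and 10 lower) and 3134 between I/R and normoxic hearts (1362 higher and 1772 lower).

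In 13 of 297 groups of 6 values the highest or lowest heart lay apart from the rest, where chance gives about 14.8, so their number is no pattern. The measure is the gap to the nearest heart over the range of the group, by Dixon's test. Among array measures it was 0.626 for the background of replicate 5 of the 32-week I/R hearts and 0.63 for its median signal, 0.879 for the detected probes of replicate 6 of the 8-week I/R hearts, 0.632 for the median signal of replicate 1 of the 48-week normoxic hearts and 0.667 for the RIN of replicate 4 of the 48-week I/R hearts. Among genes it was 0.703 for Cds1, 0.739 for Sh3gl2 and 0.65 for Tle5, all in replicate 2 of the 48-week normoxic hearts. It was 0.877 for Cdkn1a in replicate 6 of the 48-week normoxic hearts and 0.7 for Il6 in replicate 4 of the 8-week normoxic hearts. For Cct5 it was 0.756 in replicate 6 of the 16-week normoxic hearts and 0.63 in replicate 5 of the 16-week I/R hearts, and for Man1b1 it was 0.785 in replicate 5 of the 8-week I/R hearts.

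The first pattern weighed is the breadth of the I/R difference, 7743 of 9811 genes. RNA integrity as its whole cause is argued against: between 5 I/R hearts with a RIN of 8.2 or more (mean 8.28) and 8 normoxic hearts with a RIN of 8.3 or less (mean 8.20), the log2 fold changes over all genes had a slope of 0.922 (95% interval 0.88 to 0.97) on those of all hearts. Whether RIN adds to it stays open, since the slopes on RIN within groups correlated with the I/R difference at r = −0.0907 (−0.201 to 0.0851) and were themselves poorly determined (r = 0.203 between slopes from replicates 1 to 3 and from replicates 4 to 6). A difference between the arrays that is specific to probes may account for much of the breadth: pairs of bright probes of the same gene correlated at r = 0.0812, against 0.692 for age in normoxic hearts. A response to ischaemia and reperfusion stays open: over 20 genes of the acute response lists with a second probe r was 0.288 (−0.138 to 0.629), with the same sign in 12, and no label separates an array batch from the treatment.

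The second pattern is that I/R hearts of 32 and 48 weeks lay apart from those of 8 and 16 weeks, with 4831 genes between these ages against 162 in normoxic hearts. RNA integrity as its whole cause is argued against by 4 older I/R hearts with a mean RIN of 7.90 and 3 younger ones with a mean RIN of 7.70. Their difference had a slope of 0.989 (0.875 to 1.09) on the values of all I/R hearts, which include them. A share of RIN stays open (r = −0.105, −0.154 to 0.0231). A difference specific to probes may account for much of it, since bright pairs correlated at r = 0.144 (0.0534 to 0.235), against 0.623 for the same ages in normoxic hearts. Part of it may be an age difference that normoxic hearts share, which stays open: over the 4831 genes the age differences of I/R and normoxic hearts correlated at r = 0.248 (0.137 to 0.304). An effect of age on the response to I/R is part of the design and stays open too, since a batch that follows these ages could not be separated from it.

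Other splits of the same arrays, 100 for each comparison with the real one included, gave these counts. Against 8 weeks in normoxic hearts, only the real split gave as many genes at 48 weeks (161 real, 17 highest other) and at 32 weeks (154 and 18). The same held for any age (1 split, 164 and 6). With 100 splits 1 is the fewest possible, so such counts are rare among random splits, but chance is not excluded. Splits also cannot tell age or treatment apart from a batch that follows it. At 16 weeks 3 splits gave as many (4 real, 58 highest other), and for 32 against 16 weeks 2 did (5 and 9). Between 48 and 32 weeks the real count is 0, so all 100 did by construction and the splits decide nothing there (highest other 11). For I/R at 8 weeks (1 split, 5192 and 3029), 16 weeks (1 split, 5331 and 3412), 32 weeks (1 split, 6440 and 4585), 48 weeks (1 split, 6219 and 4251) and as the mean over ages (1 split, 7743 and 3355), only the real split gave as many. At each single age the highest other split moved 2 arrays, so it was the real split with 1 heart of each treatment exchanged. The median count of the other splits was 0 in each of these I/R comparisons. For the dependence on age by the F test (1 split, 2868 and 422) and for 48 against 8 weeks in I/R hearts (1 split, 3855 and 1681), again only the real split gave as many. For the change of the I/R difference between 48 and 8 weeks 2 splits gave as many, with 2097 in the real split and 2188 in the highest other. In that other split 18 arrays had moved. Splits that largely exchange the 2 ages were not left out of this draw. Whether it was such an exchange or a mixed grouping was not tested.

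The split with 58 genes set replicates 1, 2 and 6 of the 8-week and of the 16-week hearts, with a mean RIN of 8.45, against the others, with a mean RIN of 8.82. Of its 58 genes 57 were higher on that side, 56 of the 57 were higher in I/R hearts, and over all genes its log2 fold changes correlated with those of I/R at r = 0.436. Mdh2, Pmpcb and Selenop, 3 of the 8 leading I/R genes, were among the 58.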

How the results depend on the processing

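The counts of genes with both brightest probes past the threshold, the fits without each array and the contrasts over other ages were chosen as tests only after the result was seen. Of 203 values under the alternatives planned before, 175 stayed within 1.5 times the reported count or within the spread. Of 1544 values of named genes 1475 kept their direction and side of the threshold, 30 fell short of it, 39 came past it and 0 reversed. The named genes were chosen for large changes or small p on these arrays, and second probes were not compared here. Reversals were therefore unlikely by construction. The count for 48 against 8 weeks in normoxic hearts ranged from 134 to 359, that for the mean I/R difference from 4780 to 10775, and that for 48 against 8 weeks in I/R hearts from 2869 to 4714. Of 117 directions of lists past the threshold under 3 other scalings, 0 turned and 107 stayed past it. Signal over background limits the folds of dim probes, and for I/R probes of the same gene disagreed.

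The values that moved are these, and the cause was not tested except where stated. With median centring 8 genes differed at 16 weeks from 8 weeks in normoxic hearts, 235 at 32 weeks and 11 between 32 and 16 weeks, and 0 lists passed for I/R. The authors' values gave 233 genes at 32 weeks from 8 weeks, 11 between 48 and 32 weeks, 3 lists for I/R and 3 for its change with age. Without a filter 2 lists passed for I/R. The strict filter gave 8 genes between 32 and 16 weeks, and 0 lists for I/R and for its change with age. With all probes tested singly 2 differed at 16 weeks and 1 between 48 and 32 weeks. Array weights gave 20 genes at 16 weeks, 408 at 32 weeks and 359 at 48 weeks from 8 weeks, 10 between 32 and 16 weeks, 19 between 48 and 32 weeks and 438 for any age. With RIN as a covariate 2 genes differed at 16 weeks, and 3 lists passed for I/R and 0 for its change with age. A fold of at least 1.3 left 4780 genes for the mean I/R difference, a stricter criterion by construction. With an estimated correlation 0 lists passed for age, for I/R and for its change with age.

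With the replicate number as a block 0 lists passed for I/R. In 0 of 28 pairs of groups were all correlations between hearts of the same number above 0.1. Of 168 pairs of arrays with the same number 12 had r above 0.1, and r ranged from −0.212 to 0.206. That check looked at single numbers. It cannot exclude structure shared by several, as in the split of replicates 1, 2 and 6 against the others. The fit with the slide as a block was not run, since no slide is named.

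Only genes with both brightest probes past the threshold in the same direction were then counted, among 2813 genes by construction. In normoxic hearts this gave 0 genes at 16 weeks, 9 at 32 weeks and 9 at 48 weeks from 8 weeks, and 0 between 32 and 16 weeks. For I/R it gave 589 at 8 weeks, 611 at 16 weeks, 794 at 32 weeks, 697 at 48 weeks and 1074 as the mean. It gave 65 for the change of the I/R difference between 48 and 8 weeks and 246 for age in I/R hearts. F tests have no direction, so there both probes had only to pass. Such genes numbered 11 for any age in normoxic hearts and 202 for the dependence of the I/R difference on age. The I/R difference changed for 1 gene between 8 and 16 weeks and for 158 between 32 and 48 weeks, in place of 2097 between 8 and 48 weeks. Without each array in turn the count for 32 against 8 weeks ranged from 94 (without replicate 2 of the 8-week hearts) to 206, with 102 without replicate 5 of the 32-week hearts, and that for 48 against 8 weeks from 121 to 164.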

Other observations

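The correlations among clock genes other than that of Arntl with Dbp were chosen as tests only after the result was seen, and the clock genes named were chosen after their values were seen.

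Immediate early and inflammatory genes were higher at 48 than at 32 weeks in normoxic hearts (mean RIN 8.30 and 8.42) as groups, although 0 genes passed over all genes by limma (504 at an unadjusted p under 0.05). Of 29 immediate early genes 17 passed when adjusted over the list alone (median log2 fold change 0.40, adjusted p = 7.12e-26, or adjusted p = 0.0571 with an estimated correlation). Of 28 inflammatory genes 10 passed when adjusted over the list alone (median 0.56, adjusted p = 2.24e-19, or adjusted p = 0.0677 with an estimated correlation). The immediate early list went the other way between 8 and 16 weeks (median −0.18, adjusted p = 4.58e-05, or adjusted p = 0.826 with an estimated correlation) and between 8 and 32 weeks, where 2 of 29 genes were lower (median −0.19, adjusted p = 0.000139, or adjusted p = 0.63 with an estimated correlation). The endothelial list was lower at 48 than at 32 weeks (median −0.11, adjusted p = 0.00186, or adjusted p = 0.412 with an estimated correlation).

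Several genes of the circadian clock differed widely between normoxic hearts of the same age. Dbp, a clock-driven transcription factor, spanned 4.15 log2 units over the 24 normoxic hearts, and its spread pooled over the 8 groups (SD 0.942) was above that of 99.9% of genes. Arntl, the clock activator also known as Bmal1, spanned 2.72 log2 units, and the clock repressor Per2 spanned 3.40. Not all did so: the spread of Nr1d1 (SD 0.313) was above that of 74.9% of genes, and Dbp had an SD of 0.24 in the 32-week and 0.121 in the 48-week I/R hearts. None of them differed past the threshold over the ages of normoxic hearts (adjusted p = 0.617 for Dbp and 0.503 for Arntl). The clock list of 16 genes was higher at 16 than at 8 weeks in normoxic hearts, with 0 genes over all genes and 1 over the list alone (median 0.172, adjusted p = 0.00775, or adjusted p = 0.46 with an estimated correlation). At 32 weeks 1 passed over all genes and 8 over the list alone, and the list did not pass (adjusted p = 0.0812). As deviations from the group means of the 24 normoxic hearts, Arntl and Dbp moved oppositely (r = −0.901, rho = −0.914, permutation p = 1e-05, the smallest that 100000 permutations can give, adjusted p = 2.4e-05 over 12 relations). Without the 2 hearts farthest from the median r was −0.878. Arntl and Per2 had r = −0.867 (rho = −0.87), Dbp and Per2 r = 0.941 (rho = 0.943), Dbp and Per3 r = 0.939 (rho = 0.939) and Dbp and Tef r = 0.932 (rho = 0.921), each with a permutation p of 1e-05, and r was −0.839, 0.947, 0.926 and 0.928 without the 2 farthest hearts. In the 24 I/R hearts Arntl and Dbp had r = −0.755 (rho = −0.638, permutation p = 0.00228 and 0.00389, adjusted p = 0.00304 and 0.00519), and r = −0.612 without the 2 farthest hearts. Arntl and Per2 had r = −0.705 (rho = −0.666), Dbp and Per2 r = 0.769 (rho = 0.65), Dbp and Per3 r = 0.693 (rho = 0.432) and Dbp and Tef r = 0.799 (rho = 0.737). Without the 2 farthest hearts these r were −0.6, 0.526, 0.347 and 0.635. Each passed by both measures (adjusted p of 0.0098 or less for r) except Dbp and Per3 by rho (adjusted p = 0.102).

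A candidate explanation is the time of day at which each heart was taken, which the labels do not give. It calls for Arntl and its output Dbp to move oppositely between hearts of the same group, as they did (r = −0.901, 95% interval −0.943 to −0.842). RNA integrity cannot be told apart as a further source in these 24 hearts: Dbp and RIN had r = −0.238 (−0.685 to 0.343, rho = −0.213, permutation p = 0.334 and 0.363), and r = 0.0586 without the 2 farthest hearts. No biological explanation from the study's groups was tested for the spread within them. Group means differed as well. In I/R hearts the mean log2 level of Arntl was 7.53 at 8 weeks and 5.43 at 48 weeks, and that of Dbp was 10.14 and 11.89. In normoxic hearts Per2 was 6.55 at 8 weeks and 8.20 at 32 weeks (adjusted p = 0.232 over all ages, F test). Collection times that differed between ages could not be told apart from age.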
